A study of Mus musculus with 4 samples.

How the data were processed

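RNA from 4 samples of J774M cells, 2 control and 2 treated with 10 uM NC06 for 24 h, was measured on whole-transcript Affymetrix arrays, 1 array per sample. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin for a whole-transcript GeneChip. The log2 values per probe set are those the authors deposited, made with Partek per the submitters' processing notes. The version, the background correction, the normalization and the summarization were not given in the sources used here. The authors' deposited table gives a ratio of NC06 over control for each same-numbered pair and for the group means. On the log2 scale these ratios equalled the differences of the value table with a largest deviation of 2.4e-15 per pair and 8.8e-05 for the means, which settles the scale and the direction. The p-value in the authors' deposited table, listed for all but 6 of its 31873 probe sets, matched an unpaired equal-variance 2-sample test on the log2 values with a median deviation of 5.4e-06 and a largest of 0.0037. Of these, 4081 were under 0.05, 1907 with a ratio above 1 and 2174 below, and 402 of them had a change of at least 1.5-fold.

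Of 41345 probe sets, the platform annotation gave 23521 a single gene and 1820 several genes, and did not list 16004. Of the latter, 4311 took the symbol of the authors' deposited table where a RefSeq gene table of assembly GRCm38.p6, used for names only, held it. Trp53 and Bax were named in this way. The 11693 probe sets left without a name and those with several genes were not tested. The 27832 named probe sets gave 26246 genes, and for the 1284 genes with several the probe set with the highest mean was used. No genome build was named, so no coordinates are given.

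The values were used as deposited, without further normalization or filter. Differences were tested with limma 3.58.1 (lmFit and eBayes, without trend or robust options, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual and 2.36 prior degrees of freedom. Standard errors are those of the moderated fit, and intervals are 95% intervals. 28 gene lists, fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera compares the moderated t of a list's members with that of the other genes, here without ranks. Its p-values were adjusted over the lists. Members were also adjusted over the list alone. An estimated correlation and the rotation test fry were alternatives. With an estimated correlation camera takes its p from the 2 residual degrees of freedom, so an adjusted p under 0.05 was hard to reach. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

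Genes were named by a rule fixed beforehand. It took the genes of the series title, then the 10 largest rises and 10 largest falls among genes past the threshold with both NC06 arrays on one side of both control arrays and the brighter group mean above the median of tested genes, leaving out predicted or unnamed models and small RNAs. Where fewer than 10 passed, the places were filled by the largest absolute moderated t and said not to pass, which was so for all 20. The 3 members with the smallest p in each list were named with whether they pass. Some list members are not reported here, and the member with the next smallest p took the place of such a one. Further members were named as examples after their values were seen.

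Alternatives were quantile normalization, median centring, removal of the lowest signal quartile or of the genes below the median signal, a variance prior with trend and robust fitting, the mean or the dimmest probe set of a gene, the replicate number as a block, leaving out each array, the deposited ratios and p-values, an adjusted p under 0.10, a change of at least 1 log2 and limma's treat at 0.5 log2. Naming from the platform table alone was added after the data had been seen. On simulated data the fit over 26246 genes recovered 36 of 100 genes changed by 1 log2 and 83 of 100 changed by 2 log2 with 10 false calls, and over the 13123 brighter genes 90 and 100 of 100 with 9 false calls. The correlation between arrays across genes was 0.995 within each group and 0.993 to 0.994 between groups. The number of arrays limits the precision, and dim probe sets carry the least signal over background.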

Results

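Gene expression was measured in J774M, a mouse cell line that the labels class as myeloid-derived suppressor cells (MDSCs), immature myeloid cells known for restraining T cells. The 4 arrays fell into 2 groups of 2. The control cells were set against cells cultured for 24 h with 10 uM NC06, an inhibitor of neutral ceramidase. Neutral ceramidase is the product of Asah2 and splits ceramide into sphingosine and a fatty acid. What the control cells received was not given in the sources used here. Each array gave a log2 signal for 41345 probe sets. Its median was 4.68 and 4.67 on the control arrays and 4.75 and 4.74 on the NC06 arrays. With 2 arrays per group, the number of arrays limits the precision of every value. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

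The comparison of NC06 with control addresses how a ceramidase inhibitor alters gene expression in MDSC-like cells. The series title points to p53, Hmox1 and ferroptosis, a form of cell death driven by iron and lipid peroxidation. The genes with the highest moderated t among the higher ones included Ppbp, a platelet and myeloid chemokine, which was 3.60 log2 higher on the NC06 arrays (SE 0.13, 12.1-fold). Mmp8 and Mmp9, the neutrophil collagenase and gelatinase B, were 2.89 (SE 0.093) and 2.05 (SE 0.11) log2 higher. Ccr1, a chemokine receptor, was 2.22 higher, and Tgfbi, an extracellular matrix protein, 2.18 higher. Adam8, a membrane metalloproteinase, was 1.61 higher, Trp53inp1, a p53-induced nuclear protein, 1.62, Tm4sf1 1.57 and Cd300ld, an activating myeloid receptor, 1.55. Cstdc4, a cystatin family gene, read 5.84 and 5.49 log2 on the NC06 arrays and 1.96 and 1.81 on the control arrays. The control values lay below the lower quartiles of those arrays, 3.53 and 3.51, so the size of its difference is uncertain. On the lower side stood mostly genes that interferon induces. Ifit1 had a log2 change of -2.28 (SE 0.13), and Irf7, the transcription factor that amplifies interferon production, had a change of -2.25 (SE 0.15). The changes of Cmpk2, Rtp4 and Oasl2 were -2.14, -2.11 and -1.94. Ifi44 had a change of -1.70, Xaf1 -1.39, Irgm1 -1.34 and Trim30a -1.19. Chac1, an enzyme that degrades glutathione and is induced by ATF4 and CHOP, had a change of -1.93 (SE 0.12). By the rule that picked these 20 genes, both NC06 arrays lay on one side of both control arrays in each.

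None of these 20 genes passed the adjusted threshold of 0.05 in the limma fit over all 26246 genes. Their adjusted p ran from 0.0525 for Mmp8 and Ppbp to 0.0726 for Irgm1. The fit called 0 genes higher and 0 lower, with 4018 genes at an unadjusted p under 0.05, of which 2044 were higher and 1974 lower. At an adjusted p under 0.10 it held 77 higher and 40 lower genes. Both NC06 arrays lay outside both control arrays in 47.7% of the genes, against 33.3% expected by chance. A change of at least 1 log2 was seen in 60 higher and 33 lower genes. The 2 control arrays differed from each other by that much in 113 genes and the 2 NC06 arrays in 85. Those are differences of single arrays, which spread more than differences of group means. Without control replicate 1 the unadjusted count was 2506 and without NC06 replicate 1 it was 2631, and without any 1 of the 4 arrays 0 genes had an adjusted p under 0.10. Without the genes below the median signal the same fit called 451 higher and 385 lower, and with a variance prior with trend and robust fitting it called 640 higher and 819 lower. The authors' deposited table gave a p under 0.05 to 4081 probe sets, of which 0 remained after Benjamini-Hochberg adjustment of its p-values.

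**Figure D1:**
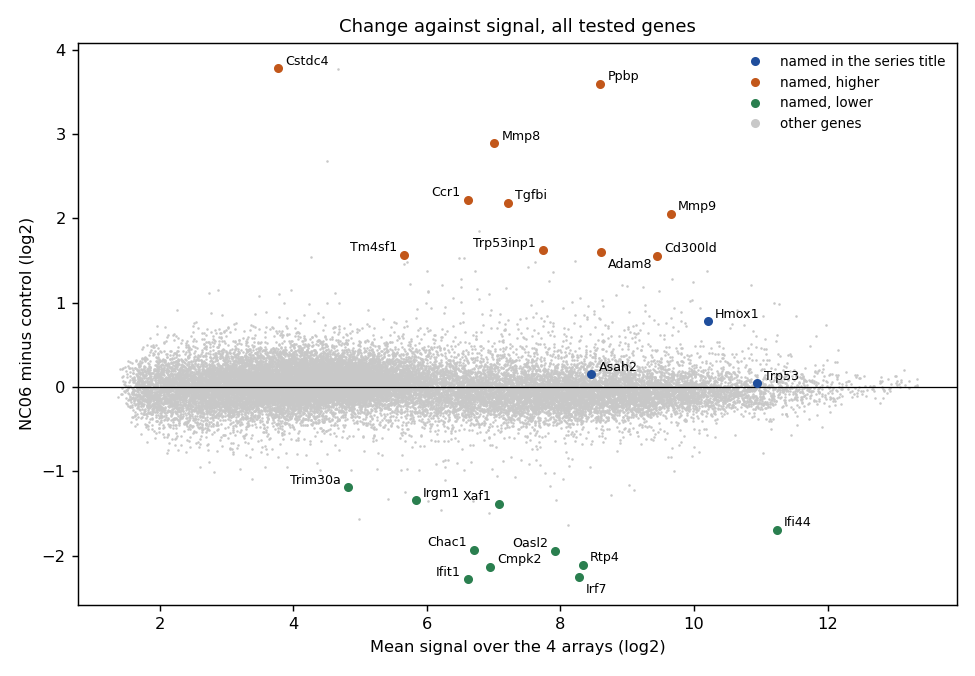
Each point is 1 of the 26246 genes tested, with its mean log2 signal over the 4 arrays on the x axis and the log2 difference of NC06 minus control on the y axis. The genes named by rank and the genes of the series title are marked, with Ppbp at 3.60, Irf7 at -2.25 and Hmox1 at 0.78.

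Hmox1 encodes heme oxygenase 1, which degrades heme and releases iron. Its signal was 9.82 ± 0.057 log2 (SD, n = 2) in control cells and 10.60 ± 0.067 (SD, n = 2) in NC06 cells. The difference was 0.78 log2, with an SE of 0.085 and a 95% interval from 0.55 to 1.01, or 1.72-fold, and both NC06 arrays lay above both control arrays. Over all genes its adjusted p was 0.103 in the limma fit. It was 0.0127 when the genes below the median signal were left out and 0.000419 with the trend and robust prior. Asah2, the target of NC06, had 8.39 ± 0.0064 and 8.54 ± 0.24 log2 (SD, n = 2). Its difference of 0.15 (SE 0.14, 95% interval from -0.22 to 0.52) was within the spread of the arrays, at an adjusted p of 0.65, and without NC06 replicate 2 it was -0.023. Trp53, which encodes p53, had 10.93 ± 0.059 and 10.97 ± 0.12 (SD, n = 2). Its difference was 0.041 (SE 0.098, 95% interval from -0.22 to 0.31, adjusted p 0.877), was -0.032 after median centring of the arrays, and was -0.043 without NC06 replicate 1 and -0.001 without control replicate 1. The groups of arrays overlapped for Asah2 and Trp53. The probe sets were 17363927 for Asah2, 17502573 for Hmox1 and 17251659 for Trp53.

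Genes that p53 is known to induce rose as a list, though not in every member. Of 37 measured members of the list, 18 rose and 1 fell when adjusted over the list alone, 0 passed over all genes, and the median change was 0.29 log2. The 3 members with the smallest p were Trp53inp1 at 1.62, the decoy death receptor Tnfrsf23 at 1.28 (SE 0.075) and Ccng1, which encodes cyclin G1, at 0.98 (SE 0.076). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 0.62 log2 (SE 0.075), Mdm2, the ubiquitin ligase of p53, by 0.33, and the death receptor Fas by 0.65. Zmat3 rose by 0.72 and Phlda3 by 0.84. Members with a role in cell death through mitochondria did not pass, with changes of 0.11 for Bax, 0.11 for Bbc3 and -0.043 for Pmaip1. The member that fell, Sesn2 at -0.46, is known also as a target of ATF4. The list was higher by camera (adjusted p = 3.27e-10), and with an estimated correlation its adjusted p was 0.275. On the same arrays the 18 neutrophil markers had a median change of 0.27 log2.

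**Figure D2:**
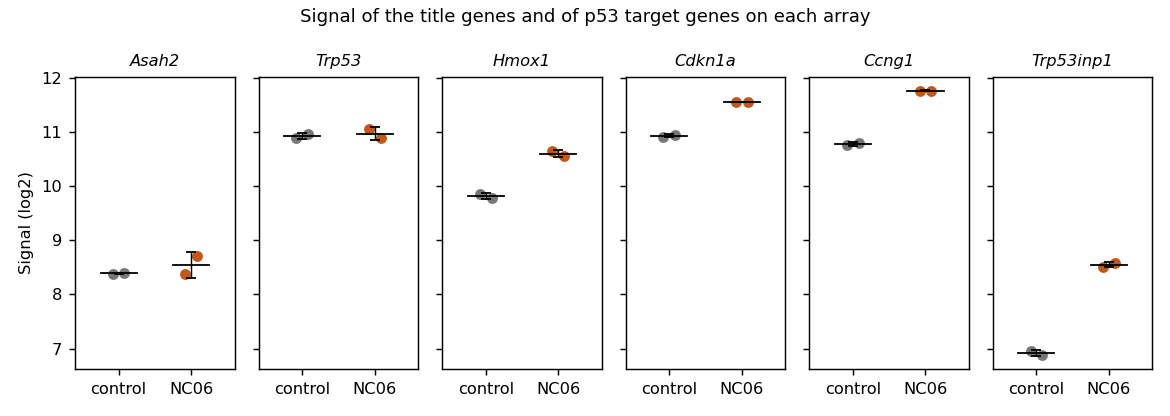
Log2 signal (y axis) of the genes of the series title and of 3 p53 target genes on each array, with 2 control arrays in grey and 2 NC06 arrays in orange, the group mean as a line and the SD as an error bar. The arrays overlap for Asah2 and Trp53, and both NC06 arrays lie above both control arrays for Hmox1, Cdkn1a, Ccng1 and Trp53inp1.

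Genes of ferroptosis and iron handling moved in both directions. Of 35 measured members 4 rose and 1 fell when adjusted over the list alone, 0 passed over all genes, and the median change was 0.002 log2. Chac1 fell by 1.93 log2. Alox5, the 5-lipoxygenase of leukotriene synthesis, rose by 1.38 (SE 0.089), Hmox1 by 0.78, the transferrin receptor Tfrc by 0.54 and the cystine transporter Slc7a11 by 0.54 (SE 0.10). Gpx4, the peroxidase that removes lipid peroxides, had a change of 0.034 (SE 0.10). Camera in limma did not call the list (adjusted p = 0.257), although it did after quantile normalization (0.034). The median was -0.071 after median centring and -0.038 without control replicate 2. The rotation test fry called it, with an adjusted p of 0.0262 for a change on balance one way and 0.00125 for a change in either direction. In either direction fry also called the markers of T and NK cells (adjusted p 0.000953) and of B cells (0.00978). That call is therefore not particular to ferroptosis. Targets of NRF2, the regulator of the antioxidant response, rose as a list with a median of 0.13 log2 over 29 members (camera adjusted p = 5.2e-05, and 0.253 with an estimated correlation). Adjusted over the list alone 7 rose and 0 fell. The 3 with the smallest p were the epoxide hydrolase Ephx1 at 0.83 (SE 0.079), Hmox1 at 0.78 and the heme transporter Slc48a1 at 0.48. Nqo1 and Gclm, at 0.18 each, did not pass.

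The type I interferon response fell most. Of 36 measured members 31 fell and 0 rose when adjusted over the list alone, 0 passed over all genes, and both NC06 arrays lay below both control arrays in 33. The median change was -0.98 log2, or 0.508-fold. The mean of the list was 7.73 and 7.93 log2 on the control arrays and 6.80 on both NC06 arrays. Rtp4, Ifi44 and Ifit1 had the smallest p. The transcription factors Stat2 and Irf9 had changes of -0.65 and -1.18, both past the threshold in the list, and the chemokine Cxcl10 fell by 1.35. Ifit3 at -0.30 and Ifi204 at -0.20 did not pass. Camera called the list (adjusted p = 7.08e-32), and with an estimated correlation the adjusted p was 0.275. The neutrophil markers, with a median of 0.27, moved the other way on these arrays.

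Genes of the integrated stress response, the amino acid and translation program run by ATF4 and CHOP, fell as a list. Of 42 measured members 23 fell and 2 rose when adjusted over the list alone, 0 passed over all genes, and the median change was -0.30 log2 (camera adjusted p = 3.27e-10, and 0.328 with an estimated correlation). Chac1, the pseudokinase Trib3 at -1.34 (SE 0.099) and the stress protein Nupr1 at -1.09 (SE 0.099) had the smallest p. Atf4 itself fell by 0.83 and Ddit3, which encodes CHOP, by 0.45. The asparagine synthetase Asns fell by 0.68 and the mitochondrial folate enzyme Mthfd2 by 0.82. The 2 that rose were Slc7a11, which NRF2 also induces, and Ndrg1, which hypoxia also induces. Endoplasmic reticulum chaperones moved the other way, with a median of 0.17 log2 over 27 members (camera adjusted p = 6.14e-05, and 0.253 with an estimated correlation). Adjusted over the list alone 0 of them rose and 1 fell, Herpud1 at -0.73 (SE 0.076), a component of protein degradation that ATF4 also induces. Edem1 at 0.39 and Sdf2l1 at 0.35 had the next smallest p without passing.

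Cholesterol synthesis fell as a list, with 13 of 26 measured members lower and 0 higher when adjusted over the list alone, 0 past the threshold over all genes, and a median of -0.27 log2 (camera adjusted p = 4.49e-11, and 0.253 with an estimated correlation). The mevalonate pathway kinases Pmvk and Mvk both fell by 0.56 and the lanosterol synthase Lss by 0.59 (SE 0.092). The sterol reductase Dhcr7 fell by 0.58 (SE 0.10) and the farnesyl diphosphate synthase Fdps by 0.54. Targets of LXR and genes of fatty acid synthesis were not called by limma's camera (22 members, median -0.044, camera adjusted p = 0.261). The rotation test fry called them, with an adjusted p of 0.0262 for a change on balance one way and 0.00163 for a change in either direction. As for ferroptosis, the call in either direction is not particular to this list. Among them Arl4c rose by 0.77 and the cholesterol exporter Abca1 by 0.60, while Acss2 fell by 0.55, Mylip by 0.39 and Srebf1 by 0.34, adjusted over the list alone.

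Genes of sphingolipid metabolism, the pathway in which ceramidase acts, were called as higher with a median of 0.096 log2 over 44 members (camera adjusted p = 0.000825, and 0.282 with an estimated correlation). The rotation test fry did not call the list, with an adjusted p of 0.0523 for a change on balance one way. Only S1pr1, a receptor for sphingosine 1-phosphate, passed when adjusted over the list alone, at 0.68 (SE 0.078). Degs1 at 0.43, a desaturase of ceramide synthesis, and the ceramide kinase Cerk at 0.53 (SE 0.10) had the next smallest p among the members reported. The acid ceramidase Asah1 had a change of 0.053 and the sphingosine kinase Sphk1 0.066. Without NC06 replicate 2 the list's median was 0.15, and after median centring it was 0.023.

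Genes of suppressive and MDSC functions rose as a list. Of 37 measured members 12 rose and 1 fell when adjusted over the list alone, 0 passed over all genes, and the median change was 0.16 log2 (camera adjusted p = 0.000208, and 0.253 with an estimated correlation). The 3 with the smallest p were Mmp9, the lectin receptor Clec4d at 1.67 (SE 0.093) and Ly6g, the surface marker of granulocytic cells, at 1.38 (SE 0.087). S100a8 rose by 1.48 and Itgam, which encodes CD11b, by 0.84. Irf8, a factor of monocyte differentiation, fell by 0.53. The classical suppressive enzymes Arg1 and Nos2 did not pass, at -0.06 each, and neither did Cd274, which encodes PD-L1, at -0.23. Of the 18 neutrophil markers, which had a median of 0.27, 3 are also members of this list. Macrophage identity genes rose too, 13 of 34 with 1 lower, Clec7a at -0.60, over the list alone, and with a median of 0.15 log2 (camera adjusted p = 2.29e-07, and 0.253 with an estimated correlation). Lysozyme 2 (Lyz2) rose by 1.21 (SE 0.096), the Fc receptor Fcgr3 by 0.86 and the macrophage surface receptor Adgre1 by 0.88. Complement C1qa at 0.043 and Mrc1 at -0.025 did not pass.

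Markers of other cell types moved on the same arrays as the gene groups above. Of 18 neutrophil markers 7 rose and 1 fell when adjusted over the list alone, with a median of 0.27 log2 (camera adjusted p = 0.000187, and 0.275 with an estimated correlation). The median was 0.15 without the lowest signal quartile of genes and 1.25 without the genes below the median signal. Only 7 of the 18 markers had a brighter group mean above the median signal. The value of 1.25 therefore rests on at most 7 markers and not on the same list. Mmp8, Ly6g and S100a8 had the smallest p, Lcn2 rose by 1.25 and the chemokine receptor Cxcr2 by 1.01. S100a9, the partner of S100a8, had a change of -0.22 without passing, the granule protein Ngp fell by 0.28, and the receptor Csf3r was at -0.09. Of 12 dendritic cell markers Itgax, Clec10a and Ccl22 rose, at 1.46, 0.47 and 0.39, with a list median of 0.077 (camera adjusted p = 0.0168, and 0.275 with an estimated correlation). That call was lost without control replicate 2 (0.0845), without NC06 replicate 1 (0.121) and after quantile normalization (0.0673), and the median was 0.13 without control replicate 1, 0.16 without NC06 replicate 2, 0.015 after quantile normalization and 0.004 after median centring. Of 8 erythroid and megakaryocyte markers Ppbp and Pf4, chemokines stored in platelets, rose, by 3.60 and 0.73, and Itga2b was at 0.20. The list median was 0.17 (camera adjusted p = 0.014, 0.363 with an estimated correlation and 0.336 without control replicate 1, where the median was 0.033). Without control replicate 2 it was 0.25. Lists of T and NK cell markers (median 0.088, adjusted p = 0.159), B cell markers (median -0.037, adjusted p = 0.361) and fibroblast and epithelial markers (median 0.096, adjusted p = 0.139) were not called, although without NC06 replicate 2 the last was (0.0369). In them Cd28 rose by 0.51 and Lck fell by 0.42 over the list alone, while Cd2 at 0.48, Ighm at -0.39, Ms4a1 at -0.35, Cd79b at 0.11, Epcam at 0.42, Pdgfrb at 0.28 and Acta2 at 0.32 did not pass.

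Inflammatory cytokines and NF-kB targets were called as higher over 38 members, with a median of 0.044 log2 (camera adjusted p = 0.0266, and 0.384 with an estimated correlation). The chemokines Ccl7, Ccl9 and Ccl2 rose by 0.82, 0.73 and 0.75, Il1b by 0.58 and Cxcl2 by 1.14, adjusted over the list alone. Tnf at -0.20 and Nos2 did not pass. After median centring the list's median was -0.029. It was 0.077 without control replicate 2. The call was lost without control replicate 1 (adjusted p = 0.173), without NC06 replicate 1 (0.0697) and with the authors' deposited ratios and p-values (0.0575).

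Genes of growth and division were lower as lists, by small amounts, with 0 members past the threshold over the list alone. Ribosome biogenesis and MYC targets had a median of -0.17 log2 over 36 members (camera adjusted p = 4.76e-07, and 0.282 with an estimated correlation), led by Rrp9 at -0.41, Srm at -0.38 and Npm3 at -0.35. Genes of DNA replication had a median of -0.12 over 44 members (adjusted p = 6.44e-06, and 0.275 with an estimated correlation), led by Mcm10 at -0.29, Pold1 at -0.38 and Gins1 at -0.28. Mitotic genes had a median of -0.085 over 47 members (adjusted p = 6.14e-05, and 0.3 with an estimated correlation), led by Ndc80 at -0.37, Cdc25c at -0.36 and Sgo1 at -0.34. Ribosomal proteins had a median of -0.13 over 45 members (adjusted p = 7.98e-05, and 0.275 with an estimated correlation), led by Rpl34 at -0.35, Rps4x at -0.24 and Rpl8 at -0.22. Nuclear-encoded genes of oxidative phosphorylation had a median of -0.076 over 45 members (adjusted p = 0.00996, and 0.328 with an estimated correlation), led by Cyc1 at -0.30, Uqcrq at -0.26 and Uqcrc1 at -0.22. Glycolysis and hypoxia genes had a median of -0.03 over 34 members (adjusted p = 0.021, and 0.328 with an estimated correlation), with Adm at -0.52, Pfkp at -0.50 and Hk2 at -0.52. Oxidative phosphorylation lost its call without control replicate 1 (0.0976, median -0.049), without NC06 replicate 2 (0.0822), after quantile normalization (0.162) and without the genes below the median signal (0.0641). Glycolysis lost it without control replicate 2 (0.129), without NC06 replicate 1 (0.0618, median -0.085), after quantile normalization (0.0876) and without the genes below the median signal (0.19), and its median was -0.07 without control replicate 1 and -0.049 without NC06 replicate 2.

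Lysosome and autophagy genes were called as higher over 46 members, with a median of 0.066 log2 (camera adjusted p = 0.00996, and 0.384 with an estimated correlation). The lipid droplet protein Plin2 rose by 0.94 (SE 0.075) and the protease Ctsl by 0.60, adjusted over the list alone, and the autophagosome protein Map1lc3b did not pass at 0.38. The median was -0.007 after median centring, and the call was lost without control replicate 1 (0.109) and without NC06 replicate 2 (0.0747). Apoptosis regulators had a median of 0.082 over 36 members (camera adjusted p = 0.0261, and 0.275 with an estimated correlation). In that list Fas rose, and Fadd at -0.40 and Bcl2l11 at 0.26 did not pass. The call was lost without control replicate 1 (0.109), NC06 replicate 1 (0.0503) or NC06 replicate 2 (0.0685), after median centring (0.109) and with the dimmest probe set of a gene (0.122). The heat shock response (median -0.061 over 23 members, adjusted p = 0.0587) and the mitochondrially encoded transcripts (median 0.071 over 10, adjusted p = 0.0914) were not called. Fkbp4 at -0.38, Stip1 at -0.24, Hspb8 at -0.30, ND3 at 0.13, COX3 at 0.13 and ND6 at 0.15 did not pass. The heat shock list was called as lower in 6 of 14 alternative settings, with adjusted p from 0.0216 with the dimmest probe set of a gene to 0.0496 without the lowest signal quartile of genes, and without control replicate 2 among them (0.0483). After median centring the mitochondrial list had a median of -0.002, and it was called as higher with the authors' deposited ratios and p-values (0.0162).

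In all, camera with its preset correlation called 21 of the 28 lists. With a correlation estimated from the 4 arrays it called 0, with adjusted p from 0.253 to 0.569. That option rests on 2 residual degrees of freedom and could hardly call a list. For macrophage identity the estimated correlation was -0.03, under the preset 0.01, yet the unadjusted camera p went from 4.09e-08 to 0.0241. Correlated members are therefore not the reason for that loss. Where the estimate was higher, as at 0.452 for the interferon list, both the correlation and the degrees of freedom raise the p. Their shares were not separated. The estimate was also above the preset for the ATF4 and CHOP list, at 0.369, and for lysosome and autophagy, at 0.153. The rotation test fry, which asks whether the genes of a list move on balance one way, called 15. Of the lists that camera called, fry did not call sphingolipid metabolism (adjusted p 0.0523), inflammatory cytokines (0.0546), mitosis (0.0538) or lysosome and autophagy (0.0538). Nor did it call dendritic cell markers (0.0523), erythroid and megakaryocyte markers (0.0523), glycolysis and hypoxia (0.0573) or oxidative phosphorylation (0.0925). After median centring of the arrays the median difference of all genes was -0.071 log2, against 0.002 as deposited, and the list medians were 0.051 for the NRF2 list, 0.096 for the chaperones, 0.082 for MDSC functions, 0.079 for macrophage identity, 0.009 for apoptosis and 0.092 for erythroid and megakaryocyte markers. Among the lower lists they were -0.20 for DNA replication, -0.16 for mitosis, -0.20 for ribosomal proteins, -0.15 for oxidative phosphorylation and -0.10 for glycolysis and hypoxia. After quantile normalization the medians were -0.078 for DNA replication, -0.04 for mitosis, -0.051 for oxidative phosphorylation and -0.05 for glycolysis and hypoxia. The list of MDSC functions had a median of 0.083 with the mean or the dimmest of a gene's probe sets and 0.29 without the genes below the median signal.

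**Figure D3:**
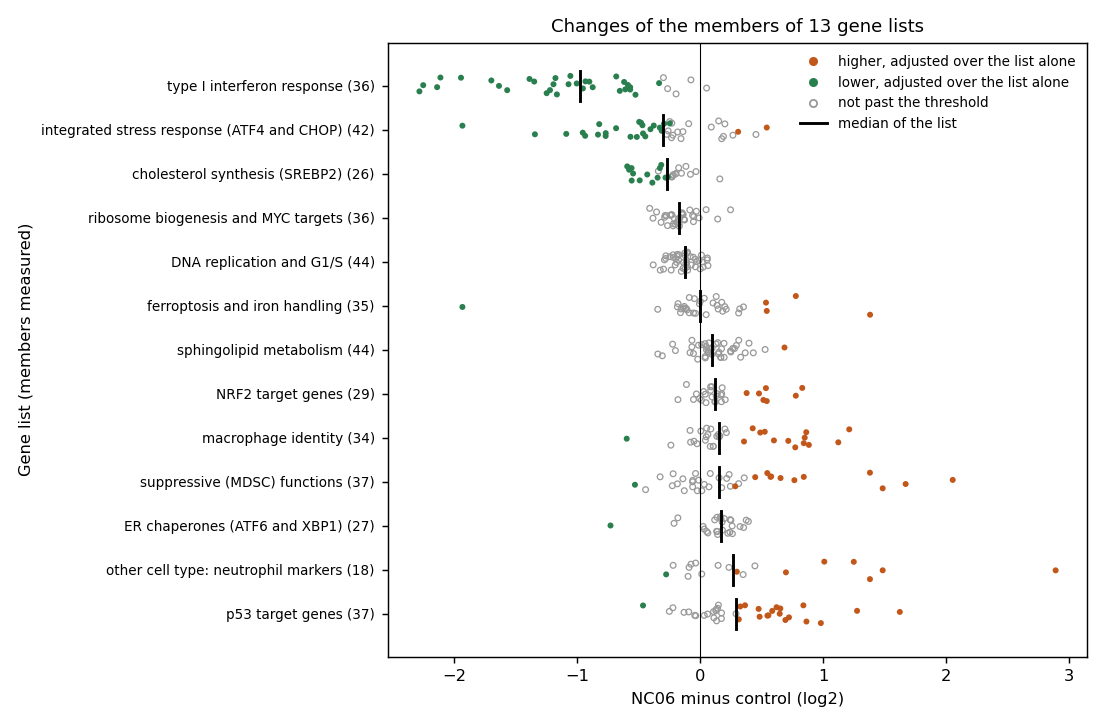
Log2 difference of NC06 minus control (x axis) for each measured member of 13 gene lists (y axis, members measured in brackets), with filled points for members past the threshold when adjusted over the list alone and a bar at the median. The interferon list has its median at -0.98 and the p53 list at 0.29, while the ferroptosis list has its median at 0.002 with members on both sides.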

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

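The counts given here were chosen after the values had been seen. Of the 11693 probe sets that neither naming source gave a gene, 276 differed by at least 1 log2 between the NC06 and control arrays, 216 higher and 60 lower with NC06, where the other splits of the same 4 arrays gave at most 191. After quantile normalization the count was 247, with 182 higher and 65 lower, against at most 188. These probe sets had a median signal of 4.25 log2, below the 4.91 of the tested genes, and they entered no comparison. Of the 1820 probe sets assigned to several genes, 2 differed by that much, both lower with NC06.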

How the results depend on the processing

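The alternatives were fixed before the data were examined, except the one restricted to names from the platform table. The count of 0 higher and 0 lower genes became 77 and 40 at an adjusted p under 0.10, 4 and 0 after quantile normalization, and 3 and 0 after median centring. It was 89 and 44 without the lowest signal quartile of genes (19684 tested) and 451 and 385 without the genes below the median signal (13123 tested). A variance prior with trend and robust fitting gave 640 and 819, the mean of a gene's probe sets 2 and 0, the dimmest probe set 2 and 0, and platform names only 47 and 16. Filtering tests fewer genes and also estimates the variance prior anew. The SE of Hmox1 was 0.069 without the genes below the median signal and 0.085 with all genes. The shares of these 2 effects were not separated. For the other changes the cause was not tested. Hmox1, at 0.778 log2 in each, passed without the lowest signal quartile (adjusted p 0.045), without the genes below the median (0.0127) and with the trend and robust prior (0.000419). Its adjusted p was 0.0691 with platform names and 0.365 with the replicate block.

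With an estimated correlation 0 of 28 lists passed, the p53 list at 0.292 having an adjusted p of 0.275. Over the other settings 15 to 22 lists were called. Leaving out 1 array gave 16 to 20 lists and 0 genes, also at an adjusted p under 0.10, assuming that the lone array varies like the others. Asah2 then ran from -0.023 to 0.32 and Trp53 from -0.043 to 0.126, with -0.032 for Trp53 after median centring. With the replicate number as a replicate block 0 genes were called (smallest adjusted p 0.222) and 21 lists. At an adjusted p under 0.10 the block left 0 genes, and it changed no other call. Deviations of same-numbered arrays correlated at 0.032 across genes, which are not independent replicates. Over all named genes and settings, 1067 values kept direction and side of the threshold, 213 passed it newly and 4 reversed. For the lists 371 kept both, 11 passed newly, 50 no longer passed and 0 reversed among those called. Direction here is that of camera, which sets a list against the other genes. The medians of inflammatory cytokines and of lysosome and autophagy were -0.029 and -0.007 after median centring, while camera called both as higher. Dim probe sets have the least signal over background.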

Other observations

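The tests of the 6 gene families, of the explanations weighed and of the array splits were chosen after the results had been seen, while the 28 lists, both correlations and the scalings were fixed before. The families were defined by symbol and tested together with camera. Replication-dependent histone genes were lower, with a median of -0.48 log2 over 26 members (adjusted p = 1.92e-12, and 0.117 with an estimated correlation), and 16 fell when adjusted over the family alone. H4c17 fell by 1.11, H2bc9 by 0.98, H2bc3 by 0.76 and H1f5, a linker histone, by 0.66. The median was -0.49 after quantile normalization and -0.55 after median centring. These genes are near-identical copies, so a probe set can read several of them and single members are uncertain. MHC class I genes had a median of -0.091 over 15 members (adjusted p = 0.0147, and 0.145 with an estimated correlation), or -0.15 after quantile normalization and -0.16 after median centring, with H2-T24 at -1.46, H2-T23 at -0.81 and H2-Q5 at -0.62 past the threshold in the family, and the call was lost without NC06 replicate 2 (0.0728).

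Several families of myeloid receptors and proteases were called as higher. They were chosen after the values had been seen, and Mmp8, Mmp9 and Cd300ld were already among the genes named by rank. The adjusted p of these families is therefore no independent support. Toll-like receptors had a median of 0.30 log2 over 12 members (adjusted p = 0.00616, and 0.215 with an estimated correlation), and 5 rose when adjusted over the family alone, namely Tlr13 by 0.94, Tlr8 by 0.90, Tlr7 by 0.44, Tlr4 by 0.41 and Tlr5 by 0.33. Tlr9 at -0.25 and Tlr3 at -0.20 did not pass, and both NC06 arrays lay below both control arrays for them. CD300 receptors had a median of 0.32 over 9 members (adjusted p = 0.000601, and 0.117 with an estimated correlation), with Cd300ld at 1.55 and Cd300lb at 1.03 higher and Cd300lg at -0.56 lower. Matrix metalloproteinases had a median of 0.12 over 23 members (adjusted p = 0.000601, and 0.117 with an estimated correlation), where Mmp13 rose by 1.22 and Mmp19 by 0.55 beside Mmp8 and Mmp9. That median was 0.039 after quantile normalization and 0.044 after median centring. Of 6 FOS and JUN genes, Fos rose by 0.95 and Fosl2 by 0.90, with a median of 0.19 (adjusted p = 0.000978, and 0.117 with an estimated correlation), or 0.12 after median centring.

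Neutrophil markers were higher on the NC06 arrays, 5 of the 18 by at least 1 log2. Under the scaling nearest to no change the list's median was 0.194 and camera called it at its preset correlation, which argues against array scaling, while with an estimated correlation its adjusted p was 0.275 as deposited. RNA from neutrophils among the NC06 cells would raise the markers together, and 8 of the 18 were higher on both NC06 arrays, 9 overlapped the control arrays, and 1, Ngp, had a 95% interval below 0. S100a9 read 3.90 and 4.37 on the control arrays and 4.08 and 3.76 on the NC06 arrays. The labels name only cells of the J774M line and no source of neutrophils, and 3 of the 18 markers are also in the list of MDSC functions. The marker values alone do not exclude RNA from neutrophils. Only 7 of the 18 markers had a control mean above the median signal, and dim markers decide little.

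Interferon-induced genes were lower, and the list's median of -0.986 under the scaling nearest to no change argues against array scaling. With an estimated correlation its adjusted p was 0.275. The group means of the list differed by -1.03 log2, 5.31 times the largest difference within a group, 0.194. A difference in interferon tone between cultures may give the same pattern and cannot be told apart from NC06, because the labels do not name separate cultures.

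Genes of ATF4 and CHOP were lower while the endoplasmic reticulum chaperones had a median of 0.169, with 22 of 27 above both control arrays. This argues against a general fall that includes the chaperone genes. Over the list alone 0 chaperones passed as higher, Herpud1 passed as lower, and the median was 0.096 after median centring. No other measure of endoplasmic reticulum stress was used here. The ATF4 and CHOP list had a median of -0.296 under the scaling nearest to no change, which argues against scaling. With an estimated correlation the adjusted camera p was 0.328 for the ATF4 and CHOP list and 0.253 for the chaperones. A less depleted medium in the NC06 cultures could lower amino acid response genes and stays open, since the glycolysis and hypoxia list had a median of -0.03, which ran to -0.10 after median centring, with members on both sides, and no measurement of the medium was used here.

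The 4 arrays can be split into equal groups in 3 ways, too few for a share under 0.05. The real split called 21 lists and the highest of the others 0, so that 1 of the 3 gave as many. These calls are at camera's preset correlation of 0.01, and with an estimated correlation 0 of the 28 lists passed in the real split.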
